A study of Homo sapiens with 8 samples.

How the data were processed

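RNA of the human cutaneous squamous cell carcinoma line HSC-5 was profiled by RNA sequencing in 8 libraries. Per the labels' protocols, the cells were grown in DMEM with serum, RNA was taken with a column kit, and libraries were made with the TruSeq Stranded mRNA kit. Per the design text of the series, the cells stably carried Cas9 and received either an empty vector or 1 of 2 guide RNAs against EZH2, and carriers were selected with G418 before RNA was taken. The same text states that the authors left out 1 control library because it clustered apart from the others. That library was not used here, so the spread between the controls may be understated.

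The authors deposited a table of read counts, whole numbers per gene with no normalization, with 1 column per library. FastQC, STAR and DESeq are named with genome build hg38, per the submitters' processing notes. Their versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping genes and of near-identical gene copies may therefore have been assigned in ways that cannot be checked, and such genes are marked as uncertain. The table held 20294 genes, 0 unnamed genes and 0 unused columns of library values. Its columns name the group of each library and no replicate number, so libraries are referred to by their order within a group. The table held no fold changes or p-values, so the alternatives planned for such values were not run.

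The library totals ran from 12.6 M to 15.5 M counts. Levels in CPM, the scaled unit of edgeR, were computed on library totals scaled by trimmed mean of M values (TMM). Genes with too few counts were removed with the filterByExpr function of edgeR at its minimum count of 10, which left 13124 genes; 3226 genes had 0 counts in every library. Gene symbols were matched to GENCODE release 29, which uses the same genome build: 19873 by symbol, 307 through the identifier of a renamed gene, and 114 not at all. Coordinates are 1-based positions of that release.

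The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a single gene comes from this test unless another tool is named. The pooled comparison set all 6 guide libraries against both controls in a fit of 2 levels, in which a difference between the guides counts as spread. The comparisons of each guide with the controls, and of the guides with each other, were contrasts of a fit of 3 groups. Standard errors (SE) of log2 fold changes were derived from the F statistic. The groups, the main tests, the alternatives to be run, 41 gene lists and the rule for named genes were fixed before the data were examined.

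Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 36 lists with at least 5 tested members. The test was fixed for the pooled comparison, and its use on the other comparisons was chosen later. Each list test was repeated with a correlation estimated from the data. The number of passing members is also given with p adjusted over the list alone. The lists covered PRC2, PRC1, HOX genes, developmental transcription factors, Merkel cell genes, CDK inhibitors, p53 targets, proliferation, histones, keratinocyte states, wound keratins, antigen presentation, interferon responses, chemokines, NF-kB targets and nucleic acid sensing. Others covered mesenchymal genes, epithelial adhesion, matrix proteases, the TGF-beta, YAP, WNT, NOTCH and EGFR pathways, hypoxia, lipid synthesis, ATF4 targets, NRF2 targets, retinoid metabolism, imprinted genes, cancer-testis genes, apoptosis, mitochondrial and ribosomal genes, and markers of 4 other cell types.

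Named genes were EZH2 and the PRC2 subunits, and the 10 largest rises and 10 largest falls of the pooled comparison among genes with adjusted p of at most 0.05. These had a mean normalized count of at least 50, an approved-style symbol, and all guide libraries on the same side of both controls. From each list that was called, or that had at least 3 passing members, up to 4 members with the smallest adjusted p were added. For the comparison of the guides the rule took the 5 largest differences each way. Genes named outside this rule are marked as chosen after their values were seen.

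A gene with 0 counts in both controls is given as a lower bound of the fold, computed against a floor of 3 counts over the 2 controls. A gene with 1 to 3 control counts is given as a ratio with its exact 95% counting interval. Such intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

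The code was tested on simulated data made from the means and depths of these libraries with 200 changed genes among 13124. In the pooled comparison it recovered 40.3% of genes changed 1.5 times, 82.1% of those changed 2 times and 93.9% of those changed 4 times, with 11 false calls among 155. A changed list was called in each of the simulated comparisons, and 0 of 40 unchanged lists was. Genes were simulated without correlation between them, so this does not show how the list test behaves where members of a list are correlated.

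Both guides were compared with the same controls. Therefore 20 data sets with unchanged groups were simulated against shared controls, to give the overlap and correlation in the absence of any change. Replicates were compared before averaging. Chi-square per degree of freedom between replicate pairs ran from 2.18 to 10.4, so no pair looked like 1 library deposited again.

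The alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors within edgeR, no count filter, each library left out in turn, a fit of 3 groups for the pooled comparison, stricter thresholds, a rank form of the list test, lists restricted to genes with a mean count of at least 50, and 10000 random lists matched on mean expression. The closing part gives their effect.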

Results

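EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 and keeps developmental genes silent. The series asked which transcripts change in HSC-5 cells, a human cutaneous squamous cell carcinoma line, when Cas9 is directed to EZH2 by either of 2 guide RNAs, sgEZH2-1 and sgEZH2-2. RNA was sequenced from 2 control libraries with the empty vector, 3 libraries with sgEZH2-1 and 3 libraries with sgEZH2-2. Library totals were 14.3 M and 15.5 M counts in the controls, 12.9 M to 14.7 M with sgEZH2-1 and 12.6 M to 14.3 M with sgEZH2-2. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

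The EZH2 transcript (chromosome 7, 148807383 to 148884321, minus strand, GRCh38) was lower in each of the 6 guide libraries than in either control. Its level was 82.7 and 84.1 CPM (counts scaled to a common library total) in the controls. With sgEZH2-1 it was 56.4, 56.3 and 48.0, and with sgEZH2-2 it was 73.9, 67.6 and 65.1 CPM. The mean of 83.4 ± 0.976 (SD, n = 2) in the controls stood against 53.6 ± 4.80 (SD, n = 3) with sgEZH2-1, or 64.2% of control. With sgEZH2-2 the mean was 68.9 ± 4.50 (SD, n = 3), or 82.5% of control. EZH2 fell with sgEZH2-1, with a log2 fold change of -0.64 and an adjusted p of 0.000529 in edgeR's quasi-likelihood test. The log2 fold change was -0.28 with sgEZH2-2 (adjusted p = 0.0699) and -0.45 with the guides pooled (adjusted p = 0.113). In the fit of 3 groups, where the difference between the guides does not add to the spread, the mean of both guides was at -0.46 (adjusted p = 0.00253). The sgEZH2-1 libraries enter the shared estimate of spread. Without the third of them the value for sgEZH2-2 was -0.26 with an adjusted p of 0.0473, and the cause of this was not tested. Without any other single guide library the adjusted p for sgEZH2-2 ran from 0.0546 to 0.214. A gene count includes transcripts that carry small insertions or deletions, so it does not measure loss of the protein.

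**Figure D1:**
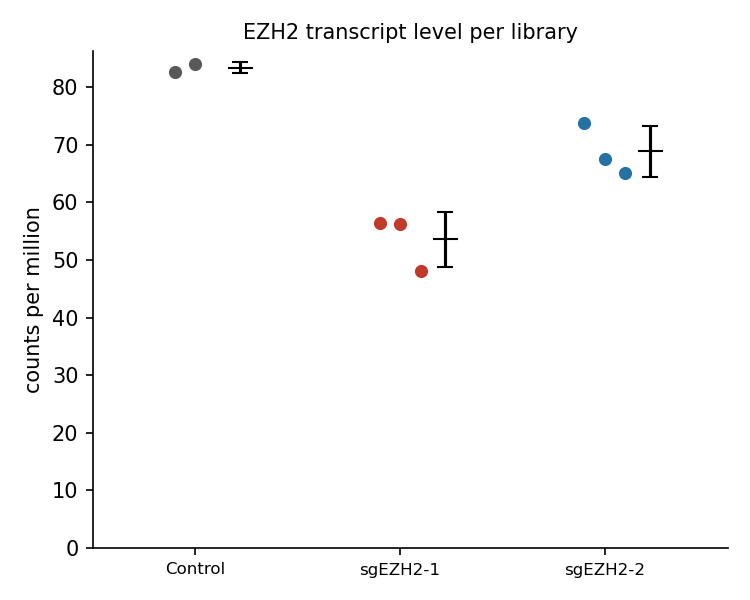
EZH2 transcript level in CPM (vertical axis) in each library by group (horizontal axis), with points for libraries and bars for the mean and SD. The controls sit at 82.7 and 84.1, the sgEZH2-1 libraries between 48.0 and 56.4 and the sgEZH2-2 libraries between 65.1 and 73.9.

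The other PRC2 subunits showed no call with the guides pooled. EED, which binds the methylated histone tail, was at 54.4 ± 2.20 CPM in the controls (SD, n = 2) and rose with sgEZH2-1 to 68.4 ± 2.22 (SD, n = 3; log2 fold change 0.33, adjusted p = 0.00538 in edgeR). The histone-binding subunits RBBP4 and RBBP7 fell with sgEZH2-1, with log2 fold changes of -0.37 (adjusted p = 0.00363) and -0.21 (adjusted p = 0.0120). With sgEZH2-2 no subunit passed the test. SUZ12, a core subunit, had pooled log2 fold change 0.20 (adjusted p = 0.336), and EZH1, the paralog of EZH2, had -0.20 (adjusted p = 0.293). The accessory subunits JARID2, AEBP2, PHF1, MTF2, PHF19, EPOP and LCOR had pooled values of -0.038, -0.0026, -0.029, 0.073, -0.047, 0.33 and 0.11. The list of 13 subunits was not called (adjusted p = 0.628).

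With both guides pooled against control, more genes rose than fell, and part of the rising genes had very low levels in the control cells. Of 13124 genes tested with edgeR, 494 rose and 78 fell. In the fit of 3 groups 1010 rose and 602 fell for the mean of both guides, so that rises made up 62.7% of calls against 86.4%. At a change of at least 2-fold, 342 rose and 3 fell. Of the 494 rising genes, 199 had a control level under 1 CPM, and 22 had 0 counts in both controls. Of the rises, 489 were also called higher with each guide in the fit of 3 groups, as were 77 of the 78 falls on the lower side. All 6 guide libraries lay on 1 side of both controls in each of the 572 called genes, and in 19.9% of all tested genes, where chance gives 7.14%. The pooled fit of the same libraries favours genes on which both guides agree, so the numbers for called genes are no separate check. The 7.14% assumes libraries that could be swapped, but the authors had left out a control that clustered apart, which favours separation. Genes are also not independent of each other, so no conclusion is drawn from the 19.9%.

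Among the genes with the strongest rises was ZDHHC2, a palmitoyltransferase gene (chromosome 8, 17156029 to 17224799). It had 0 counts in both controls and 9.35 ± 4.32 CPM with the guides (SD, n = 6), at least 92.1-fold higher (adjusted p = 0.00329). CNTNAP2, a neuronal adhesion gene with 1 count in the controls, was 174-fold higher, with a counting interval of 31.1 to 6901. GABRQ, a GABA receptor subunit, was 75.3-fold higher (25.7 to 366), and SHISAL1 was 65.2-fold higher (22.2 to 317). Each of these 2 had 3 control counts. KHDRBS3, an RNA-binding protein gene, rose by 5.20 on the log2 scale, SATB1, a chromatin organizer, by 4.74, and CAMK4, a calcium-dependent kinase gene, by 4.60.

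NEO1, which encodes the netrin receptor neogenin (chromosome 15, 73051710 to 73305206), was the most abundant of these top genes. It rose from 2.49 ± 0.294 CPM in the controls (SD, n = 2) to 60.1 ± 4.62 with sgEZH2-1 and 41.3 ± 1.87 with sgEZH2-2 (SD, n = 3 each). Its pooled log2 fold change was 4.35 (SE 0.28, adjusted p = 6.54e-05). NECTIN3, a cell adhesion gene, rose by 4.31 (adjusted p = 0.00240), and RUNX3, a Runt transcription factor gene, by 4.20 (adjusted p = 6.07e-05). RUNX3 went from 0.409 ± 0.0247 CPM in the controls to 8.03 ± 1.14 with sgEZH2-1 and 7.29 ± 0.763 with sgEZH2-2.

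Falls were smaller. TMEM52B had a log2 fold change of -1.05 (adjusted p = 0.00801), and SULT1A3, a sulfotransferase gene, -1.03 (adjusted p = 0.00110). SULT1A3 is uncertain because SULT1A4 is a near-identical copy. FGF1, a fibroblast growth factor gene, fell from 6.38 ± 0.625 CPM (SD, n = 2) to 3.41 ± 0.483 (SD, n = 6), with a log2 fold change of -0.90. ABCG2, a drug efflux pump gene, had -0.70, the caveolar gene CAVIN2 -0.68, GRAMD2A -0.65 and ACAT2, a thiolase gene of sterol synthesis, -0.64. NRG1, which encodes a ligand of the ERBB receptors, had -0.64, the amino acid transporter gene SLC1A4 -0.61, and AKR1C2, an aldo-keto reductase gene, -0.55. Their adjusted p ran up to 0.0377, for CAVIN2.

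**Figure D2:**
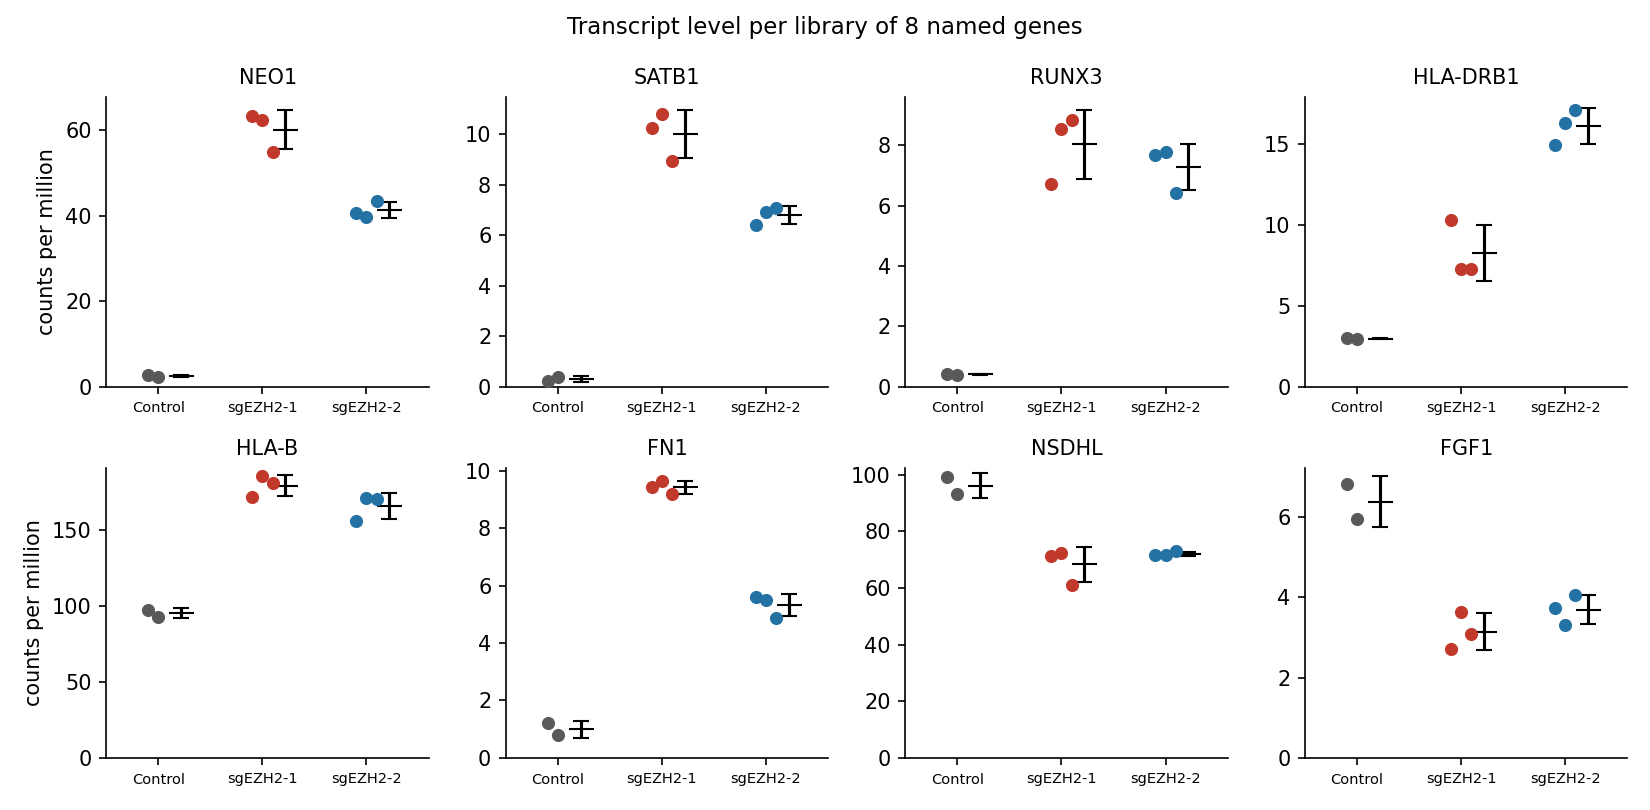
Transcript level in CPM (vertical axes, from 0) of 8 named genes in each library by group, with points for libraries and bars for the mean and SD. NEO1, SATB1, RUNX3, HLA-DRB1, HLA-B and FN1 sit higher in all 6 guide libraries than in the controls, and NSDHL and FGF1 sit lower; NEO1 goes from a mean of 2.49 to 60.1 and 41.3.

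Developmental transcription factors often marked by H3K27me3 rose as a list (median log2 fold change 0.15, adjusted p = 0.000199 with camera; adjusted p = 0.246 with an estimated correlation). Of 63 tested members 9 rose and 0 fell, or 14 and 1 adjusted over the list alone. Beside RUNX3, FOXF1, a mesodermal forkhead factor gene, had 0 counts in both controls and was at least 11-fold higher with the guides (adjusted p = 0.00201). LHX2, a LIM homeobox gene, rose by 2.96 on the log2 scale and MSX2, a homeobox gene, by 0.90. The list's median was still 0.15 with FOXF1 set to its bound. Against random lists matched on expression the list was not called (adjusted p = 0.0896). With sgEZH2-1 alone it was not called either (median 0.065, adjusted p = 0.0505): 15 members rose and 5 fell, or 17 and 5 adjusted over the list alone. With sgEZH2-2 alone 12 rose and 0 fell, or 16 and 0 adjusted over the list alone (median 0.25, adjusted p = 0.000354; adjusted p = 0.304 with an estimated correlation).

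Genes of MHC class II, which present extracellular peptides to T cells, rose as a list with the largest median, 1.69 (adjusted p = 1.62e-05; adjusted p = 0.264 with an estimated correlation). Of 11 tested members 3 rose and 0 fell, or 6 and 0 adjusted over the list alone. HLA-DPA1 rose by 2.62 on the log2 scale (adjusted p = 0.0105), HLA-DRB1 by 2.04 (adjusted p = 0.0193) and HLA-DRB5 by 1.87 (adjusted p = 0.0438). HLA-DPB1 had a value of 2.62 with an adjusted p of 0.0773. HLA-DRB1 and HLA-DRB5 share reads with each other, and HLA counts depend on how well the cell line's alleles match the reference, so these values are uncertain. Summed leukocyte markers were at 2.83 CPM in the controls and 3.52 ± 0.575 with the guides (SD, n = 6).

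MHC class I genes also rose as a list (median 0.20, adjusted p = 0.000199; adjusted p = 0.132 with an estimated correlation). Of 20 tested members 4 rose, or 6 adjusted over the list alone, and 0 fell by either count. HLA-B rose from 95.2 ± 3.24 CPM (SD, n = 2) to 173 ± 10.1 (SD, n = 6), a log2 fold change of 0.86 (adjusted p = 0.000265). HLA-F rose by 0.69, PSMB9, an immunoproteasome subunit gene, by 0.34 and HLA-E by 0.31.

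Type I interferon stimulated genes rose as a list (median 0.20, adjusted p = 6.12e-06; adjusted p = 0.132 with an estimated correlation). Of 47 tested members 7 rose and 0 fell, or 14 and 1 adjusted over the list alone. RSAD2, the antiviral gene of viperin, rose by 2.39 on the log2 scale and CMPK2, its neighbour on chromosome 2, by 2.85. HERC5, an ISG15 ligase gene, rose by 0.56 and MX1, an antiviral GTPase gene, by 0.52.

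Mesenchymal genes rose as a list (median 0.50, adjusted p = 6.12e-06; adjusted p = 0.132 with an estimated correlation). Of 25 tested members 6 rose and 0 fell, or 6 and 1 adjusted over the list alone. The matrix genes COL6A2 and FN1 each rose by 2.89 on the log2 scale and COL5A1 by 1.89, and LOX, which crosslinks collagen, by 1.65. FN1, fibronectin, was at a mean of 0.995 CPM in the controls, 9.41 with sgEZH2-1 and 5.33 with sgEZH2-2. Summed fibroblast markers were at 6.59 CPM in the controls and 9.58 ± 3.48 with the guides (SD, n = 6). COL1A1, COL1A2 and COL3A1 are on both lists, so this sum is no separate check for fibroblasts. Only 1 of the 9 fibroblast markers was tested, with a log2 fold change of -0.0095 with sgEZH2-1 and 0.88 with sgEZH2-2.

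WNT pathway genes rose as a list (median 0.24, adjusted p = 0.000199; adjusted p = 0.246 with an estimated correlation). Of 25 tested members 8 rose and 1 fell, or 10 and 2 adjusted over the list alone. AXIN2, a feedback gene of the pathway, rose by 3.49 on the log2 scale, the receptor gene FZD10 by 2.18 and the transcription factor gene TCF7 by 0.95. DKK3, of the Dickkopf family, fell with a log2 fold change of -0.51 (adjusted p = 0.00201).

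TGF-beta and BMP pathway genes rose as a list (median 0.27, adjusted p = 0.00114; adjusted p = 0.246 with an estimated correlation). Of 23 tested members 2 rose and 0 fell, or 6 and 0 adjusted over the list alone. They were the receptor gene TGFBR1, with a log2 fold change of 0.93, and CHRD, which encodes the BMP antagonist chordin. CHRD had 0 control counts and was at least 7.28-fold higher. BMP2 was at 0.99 (adjusted p = 0.0522) and LTBP1 at 0.62 (adjusted p = 0.0544).

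Epidermal differentiation genes rose as a list (median 0.48, adjusted p = 0.00218; adjusted p = 0.246 with an estimated correlation). Of 37 tested members 3 rose, or 4 adjusted over the list alone, and 0 fell by either count. Among them were PI3, which encodes a protease inhibitor of inflamed skin (log2 fold change 1.56), and the alarmin gene S100A9 (0.94). KLK8, a kallikrein gene, was at 0.74 (adjusted p = 0.0557). Basal keratinocyte genes fell as a list (median -0.14, adjusted p = 0.0449; adjusted p = 0.246 with an estimated correlation). EGFR fell, with a log2 fold change of -0.26 (adjusted p = 0.0489), as the only passing member of 19, or 2 adjusted over the list alone. JAG1 was at -0.34 (adjusted p = 0.0544), ITGA3 at 0.25 (adjusted p = 0.211) and TP63, the master factor of basal keratinocytes, at -0.58 (adjusted p = 0.278). The basal list lost its call without either control and without the first sgEZH2-1 library.

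Genes of cholesterol and fatty acid synthesis fell as a list (median -0.29, adjusted p = 5.87e-07; adjusted p = 0.362 with an estimated correlation). Of 32 tested members 4 fell, or 8 adjusted over the list alone, and 0 rose by either count. Among them were NSDHL, a sterol dehydrogenase gene (-0.45), EBP, a sterol isomerase gene (-0.35), and CYP51A1, a sterol demethylase gene (-0.33). NRF2 target genes, which serve detoxification, fell as a list (median -0.15, adjusted p = 0.00102; adjusted p = 0.246 with an estimated correlation). Of 23 members 4 fell, or 5 adjusted over the list alone: AKR1C3 (-0.51), AKR1C2 (-0.55), AKR1C1 (-0.45) and UGT1A6 (-0.27). The AKR1C genes are close paralogs and UGT1A6 shares exons with its neighbours, so their counts are uncertain. Hypoxia and glycolysis genes fell as a list (median -0.13, adjusted p = 0.00591; adjusted p = 0.497 with an estimated correlation). VEGFA, a growth factor gene of blood vessels, was the 1 of 31 members that fell, over all genes and adjusted over the list alone (log2 fold change -0.38, adjusted p = 0.00337). The others named by the rule were GPI at -0.24, ADM at -0.27 and HK2 at 0.14, with adjusted p of 0.253, 0.258 and 0.259.

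**Figure D3:**
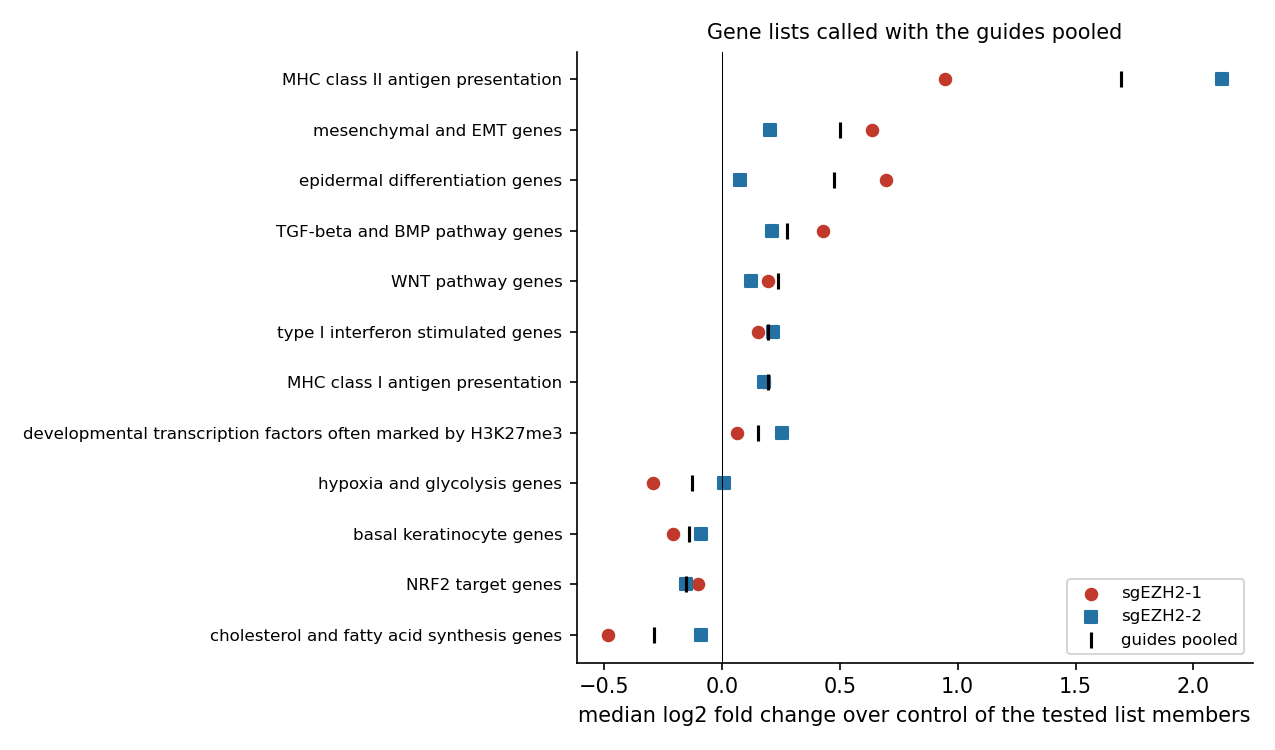
Median log2 fold change over control (horizontal axis) of the tested members of the 12 gene lists called with the guides pooled (vertical axis), for sgEZH2-1, sgEZH2-2 and the guides pooled. MHC class II stands at 0.95, 2.12 and 1.69 in that order, and cholesterol and fatty acid synthesis at -0.49, -0.088 and -0.29.

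The pooled calls rest on 2 controls: 163 genes were called without the first and 145 without the second. Of the 56 named genes that were called, 41 lost the call without a control and 14 without a guide library. The 15 that kept it without any single library were ZDHHC2, CNTNAP2, GABRQ, KHDRBS3, SATB1, NEO1, NECTIN3, RUNX3, SULT1A3, FOXF1, HLA-B, LOX, COL6A2, TCF7 and DKK3.

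With sgEZH2-1 alone, 1478 genes rose and 1248 fell against control. The falling lipid and hypoxia genes and the rising mesenchymal and differentiation genes held as lists with an estimated correlation too. Of 32 genes of cholesterol and fatty acid synthesis 28 fell and 0 rose, or 28 and 1 adjusted over the list alone (median -0.49, adjusted p = 1.42e-27 with camera; adjusted p = 0.00571 with an estimated correlation). Of 31 hypoxia and glycolysis genes 17 fell and 0 rose, or 20 and 1 adjusted over the list alone (median -0.29, adjusted p = 2.49e-13; adjusted p = 0.00571 with an estimated correlation). Of 25 mesenchymal genes 15 rose and 2 fell, or 15 and 3 adjusted over the list alone (median 0.64, adjusted p = 2.13e-09; adjusted p = 0.0435 with an estimated correlation). Of 37 epidermal differentiation genes 16 rose and 1 fell, with the same numbers adjusted over the list alone (median 0.70, adjusted p = 1.28e-06; adjusted p = 0.0435 with an estimated correlation).

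Among basal keratinocyte genes 7 of 19 fell with sgEZH2-1 and 2 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.00367; adjusted p = 0.242 with an estimated correlation). TP63 fell from 220 ± 17.1 CPM (SD, n = 2) to 109 ± 8.19 (SD, n = 3), a log2 fold change of -1.01 (adjusted p = 1.27e-05 in edgeR). JAG1 had -0.44 and GPI -0.37. KLK8 rose by 0.94, BMP2 by 1.12 and LTBP1 by 0.79. MHC class II genes rose less steeply than in the pooled view: 5 of 11 rose and 0 fell, or 6 and 1 adjusted over the list alone (median 0.95, adjusted p = 0.0136; adjusted p = 0.457 with an estimated correlation). HLA-DPA1 rose by 2.05, HLA-DRB1 by 1.47 and HLA-DPB1 by 1.69. HLA-DRB5, by 1.58, and HLA-DRA, by 0.95 and chosen after its value was seen, were the others. NRF2 targets were not called with sgEZH2-1 (median -0.10, adjusted p = 0.567), where 7 of 23 rose and 8 fell over all genes and adjusted over the list alone. The count of calls was 1373 without the first control and 1804 without the second sgEZH2-1 library.

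With sgEZH2-2 alone, 811 genes rose and 328 fell against control. MHC class II genes led: 9 of 11 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 2.12, adjusted p = 5.30e-22 with camera; adjusted p = 0.0786 with an estimated correlation). HLA-DPA1 went from 1.32 ± 0.353 CPM (SD, n = 2) to 10.8 ± 0.455 (SD, n = 3), a log2 fold change of 3.02. HLA-DPB1 rose by 3.18 and HLA-DRB1 by 2.44. Of 23 NRF2 targets 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.15, adjusted p = 6.63e-09; adjusted p = 0.0347 with an estimated correlation). AKR1C2 had -0.63 and AKR1C3 -0.57. Of 47 interferon stimulated genes 14 rose and 0 fell, or 19 and 1 adjusted over the list alone (adjusted p = 5.33e-08; adjusted p = 0.245 with an estimated correlation). Of 32 lipid synthesis genes 9 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.088, adjusted p = 0.0112; adjusted p = 0.292 with an estimated correlation).

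Hypoxia and glycolysis genes were not called with sgEZH2-2 (median 0.0071, adjusted p = 0.794). Epidermal differentiation genes were not called either (median 0.078, adjusted p = 0.169): 5 of 37 rose and 0 fell, or 8 and 0 adjusted over the list alone. Nor were basal keratinocyte genes (median -0.088, adjusted p = 0.0996) or TGF-beta and BMP pathway genes (median 0.21, adjusted p = 0.0734). Mitochondrially encoded transcripts were lower as a list (median -0.26, adjusted p = 0.00611; adjusted p = 0.458 with an estimated correlation), with 0 of 13 members passing over all genes or adjusted over the list alone. The first sgEZH2-2 library held 1.12% of its counts in these transcripts, against 1.57% in the second and 1.53% and 1.70% in the controls. The calls numbered 521 and 579 without the first and the second control, and 660 and 688 without the second and the third sgEZH2-2 library.

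The guides were then compared with each other, to see how far 1 response was shared. Against the controls, 578 genes rose with both guides and 132 fell with both. Independent lists would share 91.3 and 31.2, and simulated unchanged groups against shared controls shared 0 and 0.05. Unchanged groups give few calls, so the simulated counts cannot show what shared controls add to lists of this length. A further 25 genes rose with sgEZH2-1 and fell with sgEZH2-2, and 21 did the reverse, where independent lists would give 36.9 and 77.1. Across genes, which are not independent replicates, the log2 fold changes of the guides correlated at 0.815, against 0.609 in the simulation. The covariance was 0.369 against 0.0342 simulated, a difference of 0.335. With 2 controls these could not be split, so part of the excess may come from the shared controls.

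**Figure D4:**
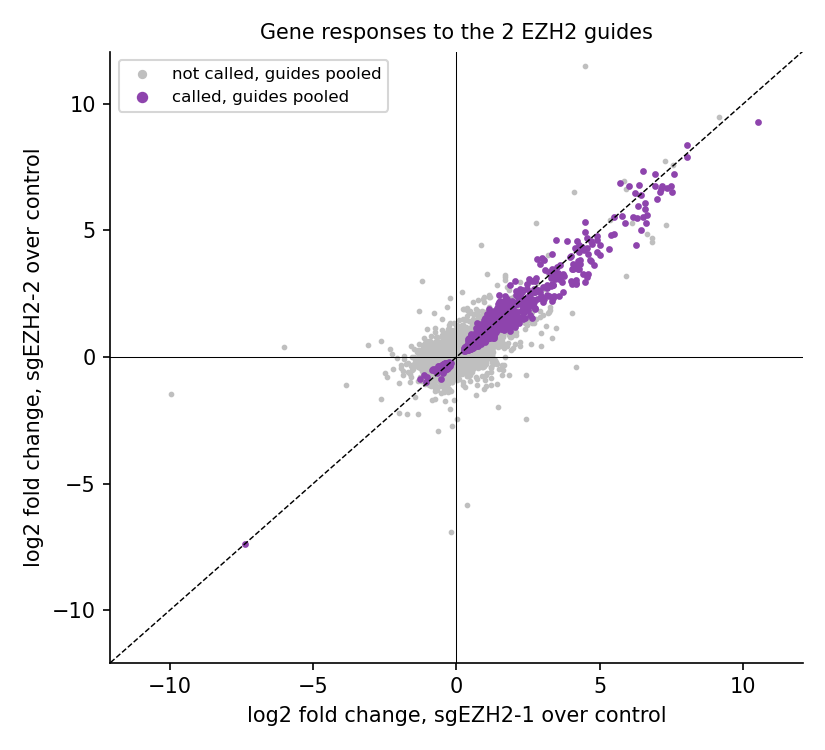
Log2 fold change over control with sgEZH2-1 (horizontal axis) and with sgEZH2-2 (vertical axis) for the 13124 tested genes, purple where called with the guides pooled (572 genes) and grey otherwise, with a dashed line of equal change. Most purple points lie in the upper right along the line, and the correlation across all genes is 0.815; fitted values of genes with 0 counts in a group depend on the prior count.

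Directly compared, 1363 genes were higher with sgEZH2-1 and 1511 higher with sgEZH2-2, of which 124 and 139 differed at least 2-fold. The 5 largest differences on the sgEZH2-1 side were KRT81, a hair keratin gene (log2 difference 2.51), the carboxypeptidase gene CPA4 (2.48), the neural adhesion gene L1CAM (2.30), the annexin gene ANXA3 (2.12) and SERPINB2, a plasminogen activator inhibitor gene (1.97). KRT81 stood at 9.79 ± 0.0825 CPM in the controls (SD, n = 2), 75.0 ± 17.1 with sgEZH2-1 and 13.2 ± 0.564 with sgEZH2-2 (SD, n = 3 each). It is uncertain because other hair keratins are close paralogs. CPA4 rose with sgEZH2-1 (1.40, adjusted p = 4.14e-05) and fell with sgEZH2-2 (-1.08, adjusted p = 0.00111).

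The 5 largest on the sgEZH2-2 side were H4C14, a histone gene (log2 sgEZH2-1 over sgEZH2-2 of -3.28), the matrix protease gene MMP10 (-2.36), the copper-binding protein gene CP (-1.82), the lipase gene CEL (-1.77) and ASB2, a ubiquitin ligase adaptor gene (-1.74). H4C14 has near-identical copies and ranged widely in the controls, 4.61 ± 5.13 CPM (SD, n = 2). CP stood at 474 ± 46.7 in the controls, 193 ± 58.7 with sgEZH2-1 and 682 ± 14.8 with sgEZH2-2. EZH2 itself was lower with sgEZH2-1 (-0.36, adjusted p = 0.00844).

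As lists, genes of cholesterol and fatty acid synthesis were lower with sgEZH2-1 than with sgEZH2-2: 25 of 32 lower and 1 higher, or 27 and 1 adjusted over the list alone (median -0.42, adjusted p = 2.17e-23; adjusted p = 0.00787 with an estimated correlation). Hypoxia and glycolysis genes were lower too, 18 of 31 and 0 higher, or 19 and 0 adjusted over the list alone (median -0.22, adjusted p = 1.18e-16; adjusted p = 0.00664 with an estimated correlation). NRF2 targets were higher with sgEZH2-1, 11 of 23 and 3 lower, or 12 and 4 adjusted over the list alone (median 0.16, adjusted p = 2.16e-05; adjusted p = 0.0445 with an estimated correlation). MHC class II genes were lower with sgEZH2-1, 8 of 11 and 0 higher, or 9 and 0 adjusted over the list alone (median -0.97, adjusted p = 2.95e-08; adjusted p = 0.187 with an estimated correlation). YAP target genes were higher with sgEZH2-1, 7 of 18 and 1 lower, or 9 and 1 adjusted over the list alone (median 0.20, adjusted p = 7.00e-10; adjusted p = 0.169 with an estimated correlation). The count of genes called between the guides was 1691 without the second sgEZH2-1 library, and 1521 and 1572 without the second and the third sgEZH2-2 library.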

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

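The tests of depth, of scaling, of the developmental gene list, of a shared response stronger with sgEZH2-1, of leukocyte markers from guide to guide and of CIITA with sgEZH2-2 alone were chosen after the results were seen, and the others were written before.

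Several named genes differed between the guides in the direct test of sgEZH2-1 against sgEZH2-2 in edgeR. Most of them passed the test with each guide against control, while EZH2, EED, RBBP4, RBBP7, TP63 and GPI passed with sgEZH2-1 alone. Among the largest rises the log2 difference, sgEZH2-1 over sgEZH2-2, was 1.25 for ZDHHC2, 0.99 for CNTNAP2, 0.97 for GABRQ and 1.41 for SHISAL1. It was 0.63 for KHDRBS3, 0.56 for SATB1, 0.98 for CAMK4, 0.54 for NEO1 and 0.84 for NECTIN3. Among genes that fell it was -0.43 for TMEM52B, 0.31 for ABCG2, -0.33 for ACAT2, -0.29 for SLC1A4, -0.20 for EBP and -0.17 for CYP51A1. In PRC2 it was -0.36 for EZH2, 0.22 for EED, -0.28 for RBBP4 and -0.16 for RBBP7.

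Among immune genes the difference was -0.31 for HLA-F, -0.97 for HLA-DPA1, -0.96 for HLA-DRB1, -1.49 for HLA-DPB1 and 0.84 for RSAD2. Among keratinocyte genes it was -0.45 for S100A9, 0.42 for KLK8, -0.21 for JAG1 and -0.77 for TP63. Among matrix and signalling genes it was 0.82 for FN1, 0.54 for COL5A1, 0.28 for TGFBR1, 0.36 for LTBP1, -0.81 for AXIN2 and -0.25 for GPI. Among the lists called with the guides pooled, medians that differed between the guides were 0.20 for epidermal differentiation, -0.97 for MHC class II, 0.28 for mesenchymal genes and 0.050 for the TGF-beta and BMP pathway. These 4 calls were lost with an estimated correlation (adjusted p = 0.0607, 0.187, 0.138 and 0.438 with camera). The medians of lists that kept the call were -0.22 for hypoxia and glycolysis, -0.42 for lipid synthesis and 0.16 for NRF2 targets. Over all 36 lists tested, 12 were called between the guides, and 3 with an estimated correlation. Of the 572 genes called with the guides pooled, 110 were also called between the guides.

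More genes rose than fell with the EZH2 guides pooled, 494 against 78. Depth did not account for it, since rises made up 88.2% (interval 85.2% to 90.9%) of 519 calls after thinning every library to 12.6 M counts, and nor did scaling, as rises made up at least 89.0% of calls under DESeq2 size factors and library totals alone, although the share was 62.7% in the fit of 3 groups. Of the 28 splits of the 8 libraries into 2 and 6 only the real 1 gave as many calls, 572 against at most 4 in the others (1 of 28), but the authors had left out a control that clustered apart, which favours the real split, and the splits count calls and not the share of rises, so chance is not excluded by them. A candidate explanation is release of genes that PRC2 silences, and the developmental list held rising calls with an odds ratio of 4.32 (interval 1.86 to 8.89, Fisher's exact test p = 0.000546). It stays open, because that test did not match expression, the list was not called against lists matched on expression (adjusted p = 0.0896), with an estimated correlation (adjusted p = 0.246) or with sgEZH2-1 (adjusted p = 0.0505), and histone marks were not measured. The controls carried an empty vector and no guide RNA. Changes shared by both guides therefore cannot be told apart from a response to guide RNA or to Cas9 cutting as such.

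The guides differed from each other in 2874 genes, and whether 1 shared response that was stronger with sgEZH2-1 accounts for part of this stays open, because the choice of genes decides the share in which sgEZH2-2 lay farther from control: 28.7% of all 2874 (interval 27.1% to 30.4%), 17.4% of the 674 also called for the mean of both guides, 4.57% of the 1466 called with sgEZH2-1 and 65.7% of the 470 called with sgEZH2-2. The changes had opposite signs in 1795 of the 2874, and each sign also depends on error in the shared controls. In the tests against control, 25 and 21 genes were called in opposite directions. Gain or loss of chromosome segments that shifts a median beyond 0.3 is argued against for the 2681 called genes in 10 Mb windows of at least 20 genes. The medians of these windows ran from -0.20 to 0.23, so that 0% of those genes lay beyond that shift. A smaller shift, from a gain or loss in some of the cells or in part of a window, stays open. The other 193 called genes were not assessed. The 6 guide libraries allow 10 splits, too few for a share under 0.05; the real split (1 of 10) gave 2874 calls in edgeR and each other split gave 0, with up to 1113 genes at an unadjusted p under 0.05. Medians of whole chromosomes, sgEZH2-1 over sgEZH2-2, ran from -0.12 on chromosome 19 to 0.062 on chromosome 13, and the cause of this was not tested. Different residual EZH2 activity, cleavage at other sites, drift of the populations during selection and technical differences between the groups of libraries were not tested.

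MHC class II genes rose with the EZH2 guides. Leukocytes in the cultures stay open: the summed leukocyte markers differed from control by 2.16% of the rise in CD74 and HLA-DRA, and 2 standard errors span -0.21% to 4.54% around the 1% that was set as the bound, while the pan-leukocyte gene PTPRC was at 0.338 CPM in the controls and 0.241 and 0.268 with the guides. From guide to guide the markers showed no such difference as the class II genes, at 0.825 CPM (SE 0.472) over control with sgEZH2-1 and 0.538 (SE 0.449) with sgEZH2-2, against 11.3 (SE 4.24) and 51.7 (SE 2.86) for CD74 and HLA-DRA, but at the bound of 1% the markers would differ by less than their error. A higher level of the class II transactivator CIITA is argued against as the cause in both guide populations, because with sgEZH2-1 its log2 change was -0.30 (-0.49 to -0.10). With sgEZH2-2 it rose by 0.44 (0.25 to 0.63, adjusted p = 0.0212), so CIITA may contribute there, and a direct effect of lower PRC2 activity on the class II genes is a further hypothesis that these data did not test.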

How the results depend on the processing

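Library totals as the only scaling, the list tests under other scalings, filters and left-out libraries, and the restriction of the gene test to a mean count of at least 50 were chosen after the data were examined. No paired analysis was possible because the columns carry no replicate numbers. The alternatives for a deposited comparison table or normalized values were not run, since the table holds counts. The Wald test of DESeq2 called 813, 2291, 964 and 2435 genes in the pooled, sgEZH2-1, sgEZH2-2 and guide comparisons, and shared 560 of the 572 pooled calls. Direction was followed only for the named genes and for the lists of the pooled comparison. Among these, no called gene or list changed direction under any alternative run. Lists that were not called did, among them NOTCH pathway, nucleic acid sensing, ribosomal protein and epithelial adhesion genes, as did uncalled PRC2 subunits near 0 such as AEBP2. Median log2 change moved by under 0.1 with scaling (-0.0043 with TMM, 0.0012 and 0.018 otherwise).

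The pooled count of 572 became 1612 in the fit of 3 groups, where the guide difference no longer counts as spread: 1010 rose and 602 fell, so the share of rises was 62.7% against 86.4%, and EZH2 was -0.46 with an adjusted p of 0.00253, past the threshold. The pooled count was 249 at an adjusted p of 0.01, 345 with a log2 change of at least 1 and 312 with a mean count of at least 50, by construction of the stricter limits. It was 557 with DESeq2 size factors within edgeR and 555 without the count filter. Leaving out each library gave 145 to 509 pooled calls, 1373 to 2591 with sgEZH2-1, 521 to 1365 with sgEZH2-2 and 1521 to 2995 between the guides. The lowest pooled counts, 145 and 163, came without a control. The remaining control is then assumed to vary like the other groups. EZH2 with sgEZH2-2 ranged from -0.32 to -0.24, and passed the threshold only without the third sgEZH2-1 library (-0.26, adjusted p = 0.0473). The cause of this was not tested.

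Of 36 lists tested, 12 were called by camera at its preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05). In the pooled fit this correlation was estimated from residuals that include the difference between the guides. It was 0.62 for lipid synthesis genes there and 0.029 with sgEZH2-1, but 0.037 and 0.095 for type I interferon stimulated genes. Random lists matched on expression, which ignore correlation between genes, called 19 of the 36 and 11 of the 12. The rank form of the list test called 16 lists, and so did the restriction to genes with a mean count of at least 50. Each kept all 12. Counting each gene and comparison under each alternative, called named genes kept the call 744 times and lost it 142 times, uncalled ones gained it 20 times, and called lists kept it 152 times and lost it 16 times. At 3 control counts or fewer, depth limits the fold of ZDHHC2, CNTNAP2, GABRQ, SHISAL1, FOXF1 and CHRD to bounds or wide intervals.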

Other observations

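The genes in the first 2 paragraphs were chosen after their values were seen, the test of the chromosome 7 segment was written before its result, and its comparison with the change of EZH2 itself was chosen after.

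Outside the called lists, single regulators rose with the guides pooled. VLDLR, a lipoprotein receptor gene, rose from 1.08 ± 0.127 CPM in the controls (SD, n = 2) to 6.57 ± 0.761 with the guides (SD, n = 6; log2 fold change 2.58, adjusted p = 0.000206 in edgeR). On the same list, of ATF4 and unfolded protein response genes, ATF4, the stress response factor, fell (-0.28, adjusted p = 0.0122). The imprinted adaptor gene GRB10 rose by 1.76, and the proapoptotic genes BMF and HRK by 1.43 and 1.04. Of 22 tested HOX genes 2 rose over all genes, HOXB9 by 3.35 and HOXD8 by 1.56, or 4 adjusted over the list alone, and 0 fell by either count. The HOX list was not called (adjusted p = 0.0640). RNF2, the ubiquitin ligase of PRC1, rose by 0.71, the chemokine genes CCL5 and CCL2 by 1.00 and 1.69, GBP4 by 0.60 and the retinoic acid hydroxylase gene CYP26B1 by 1.27. The tight junction gene CLDN1 fell (-0.51). With the guides pooled, the lists of proliferation genes and p53 targets (adjusted p = 0.461 each) and CDK inhibitors (adjusted p = 0.111) were not called by camera. There 0 members passed in edgeR over all genes or over the lists alone. With sgEZH2-1 alone 14 of 46 proliferation genes rose and 4 fell, or 15 and 4 over the list alone, while with sgEZH2-2 0 passed. The proliferation list was not called with sgEZH2-1 either (adjusted p = 0.243 with camera). Of 25 p53 targets 1 rose and 1 fell with sgEZH2-1, and 2 rose and 0 fell with sgEZH2-2.

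The genes named here differed between the guides in the direct test. SCD, a fatty acid desaturase gene, was at 3513 ± 51.6 CPM in the controls (SD, n = 2), 1627 ± 164 with sgEZH2-1 and 3626 ± 58.5 with sgEZH2-2 (SD, n = 3 each; log2 difference between guides -1.16, adjusted p = 3.59e-06). The glycolytic gene ALDOC differed by -1.47 and the hypoxia gene CA9 by -1.34. The differentiation genes KLK6, KRT80 and GRHL3 were higher with sgEZH2-1, by 1.22, 1.15 and 1.22. F3, tissue factor, rose with sgEZH2-1 (1.20) and fell with sgEZH2-2 (-0.39), as did the follistatin gene FST (1.01 and -0.89) and the cadherin gene CDH2 (0.47 and -0.93). CDH5, on the endothelial list, fell from 177 ± 4.77 to 77.3 ± 2.39 and 149 ± 8.79 CPM, and made up most of that list's summed level, 181 in the controls and 117 with the guides. Summed melanocyte markers were 29.8 and 30.5, and cancer-testis genes 1.58 and 1.47 CPM.

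The EZH2 transcript was lower with the EZH2 guides. A candidate explanation is loss of the end of chromosome 7 beyond the Cas9 site in some cells, which would also lower the genes telomeric to EZH2. With sgEZH2-1 the median log2 change of the 50 tested telomeric genes lay 0.14 below that of the other 583 genes of the chromosome (difference -0.14, bootstrap interval -0.22 to -0.031). The bootstrap resampled genes and not libraries, so its intervals leave out the spread between libraries. The interval holds the -0.2 that was set as the bound, so the test leaves a loss in some cells open. Loss of the chromosome 7 segment telomeric to EZH2 as the whole cause is argued against, since the telomeric difference lay 0.50 (0.25 to 0.77) above the log2 change of EZH2 itself, -0.64. With sgEZH2-2 the difference was -0.043 (-0.082 to 0.046), which lay 0.23 (0.031 to 0.49) above the -0.28 of EZH2.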
